A study of Homo sapiens with 6 samples.

How the data were processed

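RNA was measured in 6 libraries of sorted live erythroblasts, taken from 6 healthy donors on day 14 of a 21-day culture of CD34+ cells. Per the labels' protocols, globin mRNA and then ribosomal RNA were depleted from total RNA before paired-end sequencing. The labels give cord blood as the tissue, while the growth protocol describes adult cells. The sample characteristics were followed, and no test depends on the difference. All libraries belong to a single group, and replicate numbers follow the order of the samples and pair nothing. The libraries come from separate donors, so p-values over donors weigh a difference or relation against its variation between donors. Donor, culture and library preparation cannot be told apart. Biases of a gene or transcript that repeat in every library are not covered by these p-values.

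Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.1.0 and Bowtie were used with the genome build hg19. Each deposited file lists 41138 RefSeq transcripts, of which 34562 have an NM and 6576 an NR identifier, with the FPKM of each, its confidence bounds, its coverage and a status. The layout is that of Cufflinks, whose version, bias options and multi-read handling are not given in the sources used here. FPKM values deposited by the authors are scaled to transcript length and to the mapped fragments of the library. The coverage signal deposited by the authors is the depth of reads over a transcript. It was used only for the aligned bases per library, as coverage times transcript length summed over transcripts. Coordinates are those of the files, in hg19, counted from 1.

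How the values were made bears on what they show. Length scaling can inflate transcripts shorter than a fragment, so FPKM of RNAs of 200 nt or less can be too large or unstable. Reads shared by paralogs or by overlapping transcripts are divided by a model, so members of the histone and gamma or alpha globin families and single isoforms are uncertain. Depletion of globin mRNA makes globin levels unusable as levels in the cells. FPKM is relative to each library's total, so a few abundant genes move all others. In each library 2 to 12 transcripts had a failed estimate, and these were treated as missing. The 6 genes they belong to, HBG2 among them, were left out of the ranking of the most abundant and most variable genes. In the summed shares they count only in libraries where they have a value.

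Transcripts were summed per gene symbol (23273 symbols). Genes are called measurable at 1 FPKM or more. Logs are log2(FPKM + 0.1). Before the data were examined, 20 gene lists, 18 gene pairs, 8 isoform pairs, 5 relations and the rule for named genes were fixed. The lists were late erythroid, erythroid regulators, haem and iron, globin, erythropoietin and KIT signalling, BCL2 family, clearance and enucleation, cell cycle, replication histones, glycolysis, antioxidant, ribosome biogenesis, noncoding structural, stem and progenitor, megakaryocyte, neutrophil, eosinophil, basophil and mast, monocyte and macrophage, lymphoid, and endothelial and stromal. Named genes are the 3 highest and the 1 lowest member of each list, the 15 highest coding and 5 highest noncoding genes, both members of every pair, and the 12 genes of largest SD. Any other named gene was chosen after its values were seen. Of the fixed comparisons, 2 gene pairs and 1 isoform pair are not reported here. PKM and a few other genes were matched by the older symbol in the files.

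List levels are the median over measured members. The late erythroid list was compared with 7 lists of other lineages, and genes or transcripts of a pair with each other, by two-sided exact sign-flip tests over the 64 sign patterns of 6 within-donor differences, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Relations used Pearson's r and Spearman's rho with exact permutation p over all orders of the 6 donors. For the spread, the median SD of the members of a list was set among 10000 random lists of the same size matched on mean expression in 20 bins, as a description, since genes are not replicates. Genes whose level can reflect sex or common inherited deletions, and immune receptor and HLA genes, 165 symbols in all, were left out of the spread.

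The aligned bases were 2.89 to 3.73 Gb per library. Read counts are not used, since the files hold FPKM, and no counting intervals were computed. The steps were tested on simulated values for 5780 genes. Of 10 lists of 20 genes with their SD raised by a factor of 2, 9 were called higher, and of 200 unchanged lists of 15 genes 5 were called higher and 6 lower. Genes were simulated independently of each other, so these rates do not cover lists whose members move together between donors. The permutation test of a correlation called 7% of 100 unrelated and 94% of 50 related pairs of variables. The sign-flip test found a log2 difference of 2 with SD 0.5 in 100% of 200 simulated pairs and called 3.9% of 1000 pairs without a difference. The alternatives were other pseudocounts and minimum values, the highest transcript in place of the sum, TPM, median-ratio scaling, failed estimates as listed, list means or medians, limma on the log ratios, and 5 donors at a time. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.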

Results

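The series measured the transcriptome of human erythroblasts, the nucleated precursors of red blood cells, grown in culture from CD34+ haematopoietic stem and progenitor cells. The labels give cord blood as the tissue of origin, although a protocol text describes adult cells, and the sample label is followed here. Live cells were sorted on day 14 of a 21-day serum-free culture. The 6 libraries came from 6 healthy donors and form a single group, day 14 erythroblasts, with no treated, untreated or earlier samples. Genes, transcripts or gene lists of the same library were therefore tested side by side within a donor. Across donors, the spread was described and relations between list means were tested. Values are FPKM, fragment numbers scaled to transcript length and to the mapped fragments of the library. They were summed over the RefSeq transcripts of a gene, and log2 values are log2(FPKM + 0.1), a scale that understates the difference from low genes. Errors are SD over donors. The smallest p that a two-sided exact sign-flip test over 6 donors can give is 0.03125.

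The aligned bases over the listed transcripts came to 3.32 ± 0.27 Gb per library, from 2.89 to 3.73 Gb. A single fragment was worth 0.0147 to 0.0180 FPKM in genes with a transcript of 1500 to 2500 nt, so values of a few hundredths of an FPKM rest on very few fragments. Of 23273 gene symbols, 9225 ± 211 reached 1 FPKM in a library, and 8455 did so in all 6 libraries, of which 8148 had a coding transcript. A further 13340 symbols stayed below 1 FPKM in every library. Spearman's rho between libraries, taken across 5788 genes that are not independent replicates, had a median of 0.918 and ranged from 0.845 to 0.967 over the 15 pairs. No more than 0.01% of values above 1 FPKM were identical between any pair of libraries, so none was a copy of another.

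Short structural RNAs and histone mRNAs were the most abundant besides HBG2, a gamma globin gene at 30726 ± 3214 FPKM in the 5 libraries with a value, which is left out of the ranking of genes because its estimate failed in the other. The RNA component of RNase MRP, RMRP (hg19 chromosome 9, 35657748 to 35658015), stood at 62421 ± 10876 FPKM (SD, n = 6). That of RNase P, RPPH1 (chromosome 14, 20811230 to 20811570), stood at 40425 ± 3524 FPKM, and both genes together took 21.1% ± 1.8 of the summed FPKM. The next noncoding genes were the small nucleolar RNAs SNORA63 (5785 ± 485 FPKM), SNORA48 (5066 ± 750 FPKM) and SNORA43 (3640 ± 758 FPKM). Noncoding genes of 200 nt or less took 11.4% ± 1.01 of the summed FPKM. Length scaling can inflate transcripts shorter than a fragment, and RMRP and RPPH1 have only 268 and 341 nt. The levels, ranks and shares of these short RNAs are therefore uncertain. Of the 15 coding genes of highest mean without a failed estimate, 14 encoded replication-dependent histones and the other was the ribosomal protein gene RPS29 (2531 ± 261 FPKM). HIST1H3B (chromosome 6, 26031817 to 26032288) had 5756 ± 688 FPKM, HIST1H4C 5228 ± 783 FPKM and HIST1H4E 4355 ± 503 FPKM. The other 11 histone genes among them, HIST1H2AH, HIST1H2AI, HIST1H1B, HIST1H2AM, HIST1H3C, HIST1H2AL, HIST1H1E, HIST1H3H, HIST1H4A, HIST1H4D and HIST1H1C, lay between 2490 and 3740 FPKM. The 70 replication histone symbols took 19.9% ± 1.91 of the summed FPKM, and 81 cytosolic ribosomal protein symbols took 6.28% ± 0.56. Near-identical histone copies share reads, so the split between single histone genes is uncertain. Some of these transcripts are little longer than RPPH1, such as HIST1H4D (367 nt) and HIST1H4C (390 nt). Length scaling may therefore also bear on histone levels, ranks and their share. The 10 most abundant genes held 33.9% ± 2.45 and the 100 most abundant 62.8% ± 2.53 of the summed FPKM. All these shares leave HBG2 out in replicate 2, where its estimate failed, and without that library the top 10 held 34.6%. With globin and noncoding genes left out, the top 10 held 13.6%.

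Genes of the mature erythroid cell were high in every library. All 26 members of the late erythroid list, which holds membrane, cytoskeletal and haem genes of the red cell, reached 1 FPKM in each library, and 25 had a mean of at least 10 FPKM. The median member stood at 95.6 ± 17.1 FPKM, or 6.56 ± 0.27 on the log2 scale. AHSP, the chaperone of free alpha globin (chromosome 16, 31539203 to 31540124), had the highest mean at 1566 ± 288 FPKM. SLC4A1, which encodes the band 3 anion exchanger (chromosome 17, 42325758 to 42345502), followed at 904 ± 237 FPKM, and SLC25A37, the mitochondrial iron importer mitoferrin, at 614 ± 251 FPKM. TSPAN33 was the lowest member at 2.24 ± 1.19 FPKM. Among 18 erythroid transcription regulators, all of which reached 1 FPKM in every library, the median was 35.9 ± 8.08 FPKM. KLF1, an activator of erythroid genes (chromosome 19, 12995237 to 12998017), led at 406 ± 65.5 FPKM, ahead of NFE2 (224 ± 43.2 FPKM) and the repressor GFI1B (137 ± 11.8 FPKM), and RUNX1 was lowest at 3.69 ± 1.01 FPKM. Both lists stood at percentile 100 of random lists of the same size, as did 9 of the other 18 lists, and the neutrophil list stood at 96.7.

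Haem synthesis and iron genes had a median of 79.9 ± 12.3 FPKM over 25 members, 24 of which reached 1 FPKM in every library. The ferritin light chain gene FTL (chromosome 19, 49468566 to 49470136) stood at 981 ± 157 FPKM and the transferrin receptor gene TFRC (chromosome 3, 195776155 to 195809032) at 776 ± 188 FPKM. The haem-degrading oxygenase gene HMOX1 was lowest at 1.1 ± 0.74 FPKM. Globin mRNAs were depleted before sequencing, so their values do not give their share in the cells. HBG2, one of the gamma globin genes (chromosome 11, 5274421 to 5276011), was the highest of them. HBG1 (1812 ± 569 FPKM) is a near-identical copy, which leaves the split between them uncertain. HBM followed at 1181 ± 471 FPKM, and HBE1 was the lowest of the 10 globin genes at 13.5 ± 4.73 FPKM. All globin genes together held 7.08% ± 1.38 of the summed FPKM in the libraries with a value for HBG2.

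Cell cycle genes were also expressed throughout, with all 22 members at a mean of at least 10 FPKM and a median of 59.1 ± 7.20 FPKM. The replication clamp gene PCNA stood at 240 ± 49.7 FPKM, and the replicative helicase genes MCM7 and MCM5 at 227 ± 45.0 and 125 ± 25.7 FPKM. MCM6, a gene of the same helicase, was the lowest member at 24.5 ± 8.07 FPKM. The 15 replication histones of the fixed list had a median of 1870 ± 336 FPKM, with HIST2H2BE lowest at 180 ± 32.1 FPKM. Ribosome biogenesis genes had a median of 19.9 ± 8.02 FPKM over 15 members. NPM1 (141 ± 36.2 FPKM), NCL (103 ± 34.2 FPKM) and FBL (79.7 ± 14.3 FPKM), which encode abundant nucleolar proteins, led this list, and BOP1 (1.76 ± 0.60 FPKM) was lowest.

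Glycolysis genes had a median of 49.1 ± 8.95 FPKM, led by GAPDH (585 ± 70.7 FPKM), ALDOA (246 ± 61.0 FPKM) and the glucose transporter gene SLC2A1 (217 ± 61.1 FPKM), with the hexokinase gene HK2 lowest at 1.46 ± 0.46 FPKM. In the antioxidant list, whose median was 49.5 ± 8.49 FPKM, the peroxiredoxin gene PRDX2 stood at 1289 ± 162 FPKM. The catalase gene CAT (243 ± 38.1 FPKM) and the thioredoxin gene TXN (167 ± 26.2 FPKM) came next, and the transcription factor gene NFE2L2 was lowest at 7.69 ± 0.94 FPKM. The erythropoietin and KIT signalling list had a median of 9.95 ± 1.34 FPKM. PIM1 (266 ± 50.4 FPKM) and CISH (59.4 ± 11.6 FPKM), both known targets of STAT5, and the erythropoietin receptor gene EPOR (62.6 ± 10.3 FPKM) were its highest members, and SOCS3 (1.99 ± 0.58 FPKM) its lowest. BCL2 family genes had a median of 15.7 ± 4.94 FPKM, with BCL2L1 at 60.2 ± 25.1 FPKM, the mitophagy receptor gene BNIP3L at 46.9 ± 17.2 FPKM, BAX at 41.1 ± 5.60 FPKM and BCL2 lowest at 0.82 ± 0.26 FPKM. The list of organelle clearance and enucleation genes had a median of 16.6 ± 3.12 FPKM. Its highest members were FBXO7 (125 ± 20.04 FPKM), LMNA (97.0 ± 17.0 FPKM) and GABARAP (74.7 ± 21.4 FPKM), and its lowest was TRIM10 (0.39 ± 0.30 FPKM). TRIM10 has 16 listed transcripts, in part on an alternate haplotype of chromosome 6. Its low value may therefore depend on the multi-read handling, which is not known. Of the noncoding structural RNAs, 9 of 13 listed symbols were measured, with a median of 100.3 ± 18.1 FPKM. After RMRP and RPPH1 came SCARNA2, a Cajal body RNA, at 738 ± 108 FPKM, and DANCR was lowest at 40.2 ± 19.0 FPKM.

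**Figure D1:**
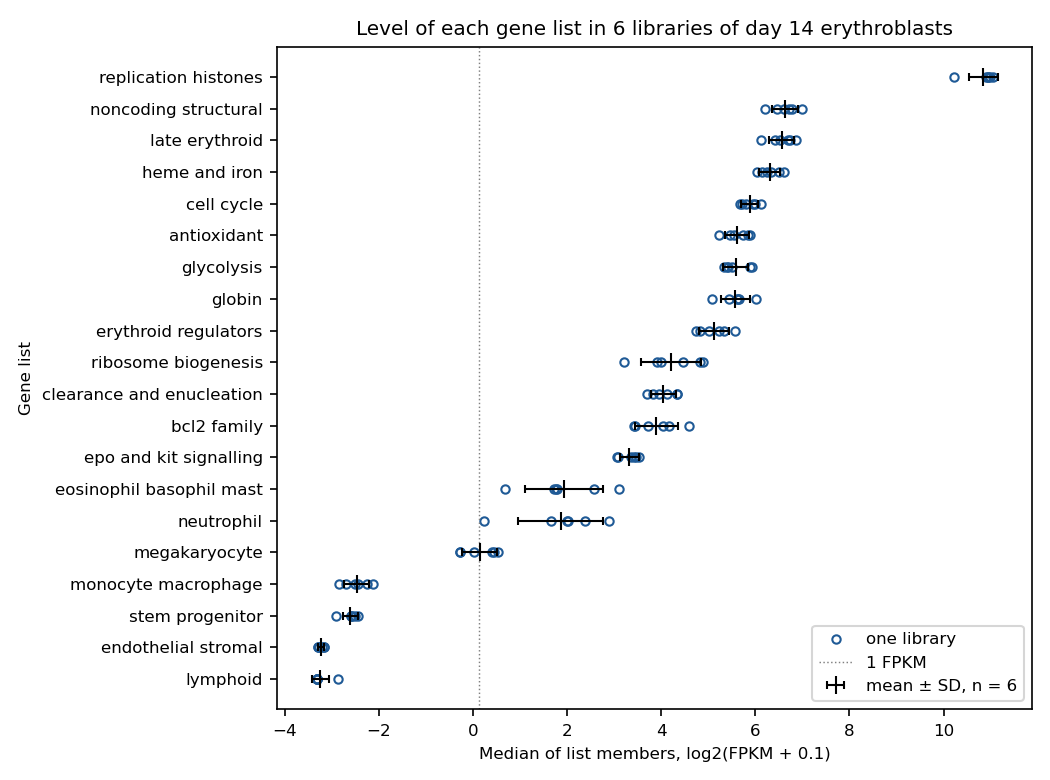
Median level of the members of each of 20 gene lists, on the log2(FPKM + 0.1) axis, in 6 libraries of day 14 erythroblasts. Open circles are libraries, the bar is the mean with its SD, and the dotted line marks 1 FPKM. The late erythroid list averaged 6.56, and the lymphoid and endothelial and stromal lists averaged −3.25 and −3.23.

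To see which other cell types the live gate held, the late erythroid list was set against 7 lists of other lineages in the same library. The late erythroid median was higher than each of them in 6 of 6 donors, with an exact sign-flip p of 0.03125 and an adjusted p of 0.03125 over the 7 comparisons, the smallest this design allows. The lists were fixed with the cell type known, so the direction was foreseeable, and the sizes of the differences tell more than the p. The difference on the log2 scale was 9.16 ± 0.17 for stem and progenitor genes, 9.03 ± 0.47 for monocyte and macrophage genes, 9.80 ± 0.29 for lymphoid genes and 9.79 ± 0.25 for endothelial and stromal genes. It was smaller for megakaryocyte genes (6.42 ± 0.47), neutrophil granule genes (4.69 ± 0.98) and eosinophil, basophil and mast cell genes (4.62 ± 0.93). Differences from lists near 0 FPKM are set largely by the pseudocount, and they fell to between 6.46 and 6.56 for the 4 lowest lists with a pseudocount of 1. With members of at least 1 FPKM alone, the stem and progenitor difference was 3.29.

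Several progenitor and granulocyte genes were nonetheless measurable. In the stem and progenitor list 3 of 15 members reached a mean of 1 FPKM, namely MLLT3 (11.05 ± 1.53 FPKM), the stem cell factor receptor gene KIT (10.8 ± 3.65 FPKM) and GATA2 (5.04 ± 1.62 FPKM), all of which erythroid progenitors also express. THY1 was listed at 0 in all 6 libraries. In the megakaryocyte list 6 of 12 members did so, led by TUBB1 (18.1 ± 5.24 FPKM), PF4 (4.14 ± 1.58 FPKM) and ITGA2B (3.47 ± 0.70 FPKM), with VWF lowest at 0.034 ± 0.015 FPKM. In the neutrophil list 8 of 12 members did so, with lysozyme LYZ at 18.3 ± 8.11 FPKM and the granule genes MPO at 13.8 ± 6.71 FPKM and ELANE at 7.29 ± 4.25 FPKM, and CAMP lowest at 0.036 ± 0.040 FPKM. In the eosinophil, basophil and mast cell list 7 of 11 members did so. PRG2, which encodes the eosinophil granule major basic protein (chromosome 11, 57154834 to 57158130), stood at 91.6 ± 25.7 FPKM, the mast cell tryptase gene TPSAB1 at 13.2 ± 9.02 FPKM and CLC at 12.7 ± 10.5 FPKM, with IL5RA lowest at 0.044 ± 0.033 FPKM. None of the monocyte and macrophage, lymphoid, or endothelial and stromal members reached a mean of 1 FPKM. Their highest were CD68 (0.999 ± 0.149 FPKM), SPI1 (0.78 ± 0.49 FPKM) and CD14 (0.38 ± 0.20 FPKM) in the first list, NKG7 (0.61 ± 0.21 FPKM), CD79A (0.094 ± 0.061 FPKM) and GNLY (0.066 ± 0.099 FPKM) in the second, and ACTA2 (0.30 ± 0.092 FPKM), PECAM1 (0.12 ± 0.045 FPKM) and PDGFRB (0.048 ± 0.036 FPKM) in the third. MS4A1 and COL1A1 were listed at 0 in all 6 libraries and MARCO in 5, values that at this depth do not show absence.

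The next comparison asked which member of related or opposing gene pairs was the higher within a donor, and 15 of the 16 pairs reported passed the test. In 12 of these the first gene was higher in 6 of 6 donors, and in 3 it was lower in 6 of 6. Each had an exact sign-flip p of 0.03125, or 0.0352 adjusted over the 18 pairs tested, which bounds what 6 donors can show. Genes of a library can differ by many log2 units, while the median SD between donors was 0.28, so a pass is easily reached. No share of passes among random pairs was computed, so the number of passes is not a result in itself. GATA1, the main erythroid GATA factor, exceeded GATA2 24.6-fold (log2 difference 4.62 ± 0.47) and exceeded SPI1, the myeloid factor PU.1, by 7.29 ± 0.74. KLF1 exceeded the megakaryocytic factor gene FLI1 by 9.97 ± 0.32 and the progenitor factor gene MYB by 5.44 ± 0.60. The erythroid enzyme gene ALAS2, at the first step of haem synthesis, exceeded its ubiquitous counterpart ALAS1 59.2-fold (5.89 ± 0.28). EPOR exceeded KIT 5.97-fold (2.58 ± 0.59), and TFRC, for iron uptake, exceeded the iron exporter SLC40A1 22.0-fold (4.46 ± 0.36). The erythroid and liver pyruvate kinase gene PKLR exceeded PKM, listed as PKM2, 6.51-fold (2.70 ± 0.56). SLC2A1 exceeded SLC2A3 by 6.93 ± 0.40, FOXO3 exceeded FOXO1 by 5.80 ± 0.57, the integrin gene ITGA4 exceeded ITGA2B by 3.60 ± 0.32, and BCL2L1 exceeded BCL2 by 5.97 ± 0.94. The ferritin heavy chain gene FTH1 was lower than FTL (−2.28 ± 0.40), LMNB2 lower than LMNA (−1.8 ± 0.12) and STAT5A lower than STAT5B (−1.14 ± 0.65).

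For the remaining pair the ratio was not distinguishable from equality. The 2 anti-apoptotic genes BCL2L1 and MCL1 differed by 0.48 ± 0.70, higher for BCL2L1 in 5 of 6 donors, with an exact sign-flip p of 0.156 and an adjusted p of 0.165.

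**Figure D2:**
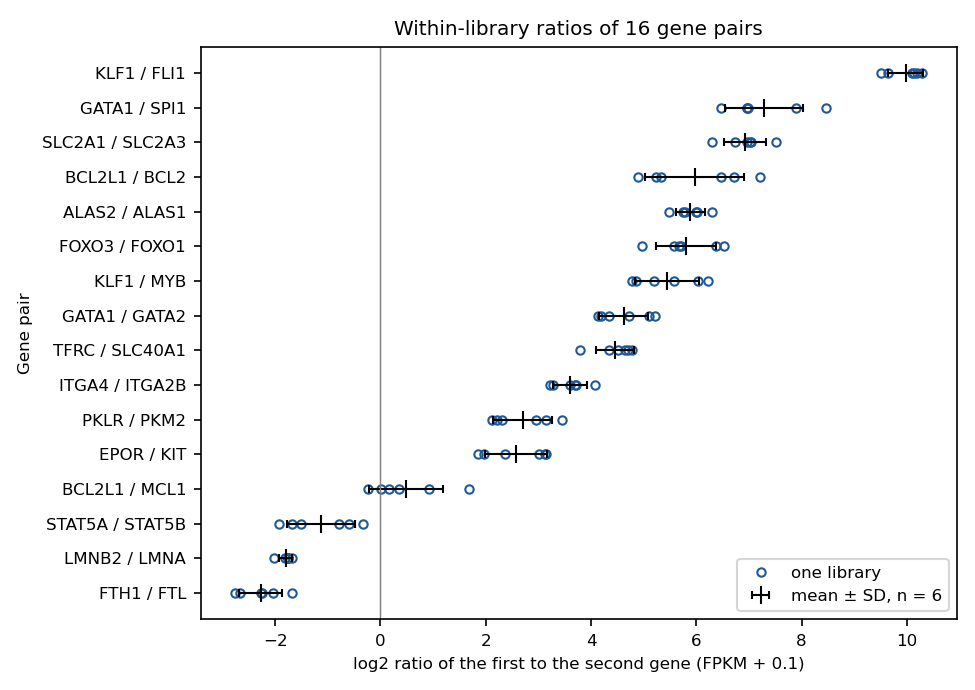
Log2 ratio of the first to the second gene of 16 pairs, on FPKM + 0.1. Open circles are the 6 libraries and the bar is the mean with its SD. The circles of BCL2L1 and MCL1 lie on both sides of 0, and the other 15 pairs lie on 1 side in all 6 libraries.

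Alternative transcripts of 7 genes were compared in the same way, and LMNA and RUNX1 are the pairs in which both transcripts had values in at least 4 libraries. The R type transcript of PKLR (NM_000298, 61.1 ± 17.0 FPKM), the long anti-apoptotic form of BCL2L1 (NM_138578, 60.2 ± 25.1 FPKM), the M2 form of PKM2 (NM_002654, 9.20 ± 1.94 FPKM) and the XL form of BCL11A (NM_022893, 4.98 ± 0.65 FPKM) were measured, while the L type of PKLR, the short BCL2L1, the M1 form and the L form of BCL11A were listed at 0 in all 6 libraries. The long MCL1 transcript NM_021960 had 40.1 ± 9.01 FPKM, and the short one was listed at 0 in 5 libraries. LMNA was read mainly as lamin C (NM_005572, 83.9 ± 16.5 FPKM), which was 6.32-fold above lamin A (NM_170707, 13.1 ± 1.79 FPKM) and higher in 6 of 6 donors (exact sign-flip p = 0.03125, adjusted p = 0.03125). Transcript c of RUNX1 (NM_001754) stood at 1.67 ± 0.34 FPKM and was higher than transcript b (NM_001001890) in 6 of 6 donors (exact sign-flip p = 0.03125, adjusted p = 0.03125), with transcript b listed at 0 in 2 libraries. Transcript c made up 46.3% of the gene and transcript b 9.97%. The remaining listed transcript of RUNX1 was not compared. A transcript listed at 0 can be an estimate that gave all shared reads to its partner, so no difference is given against it, and the sign-flip outcome of the 5 pairs with such a partner in 5 or 6 libraries was fixed by the zeros and is not counted as a test.

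The spread between donors was described for 5780 genes with a mean of at least 5 FPKM, whose SD on the log2 scale had a median of 0.28. Genes of ribosome biogenesis and of granulocytes and mast cells varied most among the lists. The median SD was 0.60 for 13 ribosome biogenesis genes, against 0.28 for random lists matched on mean expression, 0.82 for 4 neutrophil genes against 0.28, and 0.93 for 5 eosinophil, basophil and mast cell genes against 0.28. Globin genes (0.43 over 9 genes against 0.27) and glycolysis genes (0.40 over 17 genes against 0.28) also lay above the outer 2.5% of 10000 matched lists. The other 11 lists with enough members lay within it, among them late erythroid genes at 0.30, cell cycle genes at 0.29, erythroid regulators at 0.27 and haem and iron genes at 0.25. The position of the globin list ended without replicate 2 (percentile 96.8) or replicate 5 (97.4), that of glycolysis without replicate 4 (94.7) and that of neutrophil genes without replicate 2 (97.2). Without replicate 2 the globin list held 10 genes, as HBG2, whose estimate failed there, came in, so its members changed too. Globin mRNA was depleted before sequencing, so the globin spread need not be that of the cells. The neutrophil median SD was 0.51, over 6 genes, without replicate 4. That of ribosome biogenesis genes was 0.42 against 0.21 (percentile 100) without replicate 3, the library with the lowest mean of this list and of the histone list, the fewest aligned bases and the lowest scale factor. Late erythroid genes lay above the matched range without replicate 3 (percentile 99.9) and replication histones below it (1.84, with a median SD of 0.14 against 0.19). BCL2 family genes lay above it with a minimum mean of 1 FPKM (99.3) and with the highest transcript of each gene (99.5). Libraries differed in scale, with median-ratio factors of −0.29 to 0.22 on the log2 scale. After rescaling by these factors 10 lists lay above the matched range, the same 5 with the late erythroid, regulator, erythropoietin and KIT, BCL2 family and clearance lists.

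**Figure D3:**
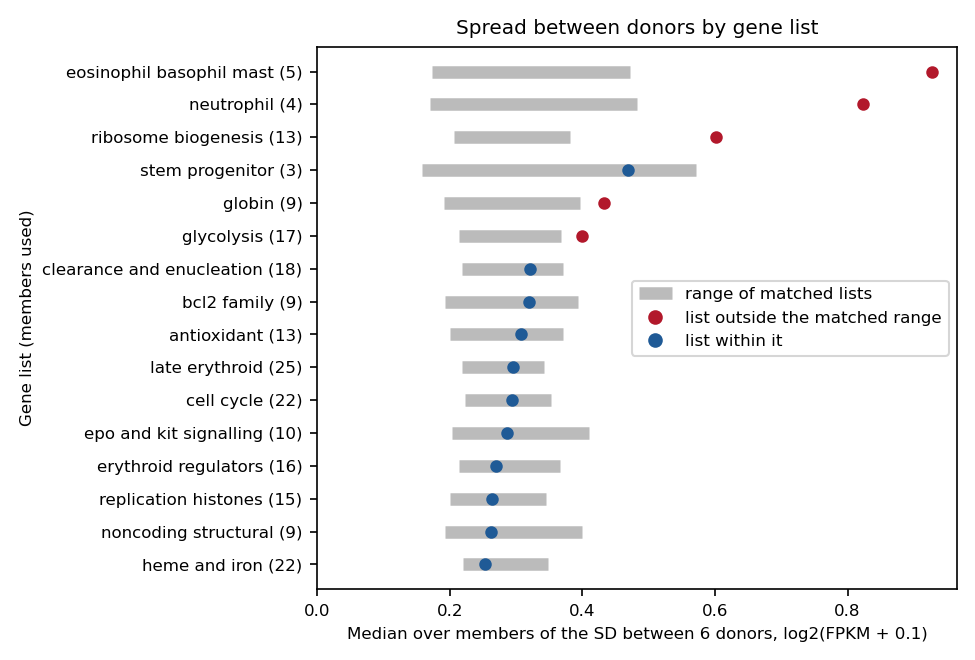
Median SD between 6 donors of the members of 16 gene lists, on the log2(FPKM + 0.1) scale, with the number of members used in parentheses. Grey bars hold all but the outer 2.5% at each end of 10000 random lists of the same size matched on mean expression, and red points lie outside them. Ribosome biogenesis (0.60), neutrophil (0.82) and eosinophil, basophil and mast cell genes (0.93) lie farthest above their bars.

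The 12 genes of largest SD were SNORD12B, MIR4305, MIR7-1, MIR3939, SNORA11B, HSPE1, SNORA56, SNORA78, SNORA36A, MIR192, MIR3936 and SCARNA8. Of these, 11 are noncoding genes of 102 to 131 nt and HSPE1, which encodes a mitochondrial chaperone, is the only coding gene. All 12 were listed at 0 in 2 to 5 libraries. Their SD ran from 4.97 to 8.04 and their range from 9.53 to 16.56 on the log2 scale. A stricter set of 4292 coding genes, chosen after these values were seen, kept genes of at least 300 nt that were above 0 in every library and overlapped no other symbol. It was led by the metallothionein gene MT1X (SD 1.67), the mitophagy gene BNIP3 (1.57), TRIB3 (1.45), TUBB (1.37) and TPSAB1 (1.31). The same 5 lists lay above the matched range in it.

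Whether donors differed together along the late erythroid list was asked with 5 relations between list means over the 6 donors. None passed the adjusted threshold. The late erythroid and the clearance and enucleation lists had a Pearson r of 0.886 (exact permutation p = 0.0306, adjusted p = 0.153) and a Spearman rho of 0.829 (exact permutation p = 0.0583, adjusted p = 0.292), with r at 0.839 without the 2 donors farthest from the median. With list medians in place of means its adjusted p by the exact permutation test was 0.0139. For ribosome biogenesis r was −0.489 (exact permutation p = 0.333) and rho −0.60 (exact permutation p = 0.242), with r −0.380 without the farthest 2, and r was −0.897 (exact permutation p = 0.0569, adjusted p = 0.0949) after median-ratio rescaling. For stem and progenitor genes r was −0.302 (exact permutation p = 0.542) and rho −0.486 (exact permutation p = 0.356), with r −0.243 without the farthest 2. The sign of this relation turned with list medians, where r was 0.788 (exact permutation p = 0.0736, adjusted p = 0.184) and rho 0.60, and r was −0.647 after median-ratio rescaling and −0.507 with a pseudocount of 1. For cell cycle genes r was 0.340 (exact permutation p = 0.499) and rho 0.086 (exact permutation p = 0.919), with r 0.010 without the farthest 2, but r rose to 0.972 (adjusted exact permutation p = 0.0417) after median-ratio rescaling, where rho was 0.771, and was 0.163 with list medians. For neutrophil genes r was −0.167 (exact permutation p = 0.785) and rho 0.086 (exact permutation p = 0.919), while r was 0.898 over the 4 donors left without the farthest 2. Adjusted p-values of these 4 relations were 0.677 to 0.785 for r. None of the 5 relations was set against random lists, so shifts shared by many genes, before or after rescaling, can contribute to r. The largest gap between neighbouring donors was 0.327 to 0.521 of the range of a list mean, and no separate clusters were defined.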

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

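The tests of short RNAs, of overlapping transcripts, of depth and of the scaling of the neutrophil list, and the correlation without single libraries, were chosen after the results were seen. The late erythroid relation and the rescaled spread were planned, but their use as tests of an explanation was not. The 9 results below have 1 library far from the other 5 by the ratio of its gap to the whole range. Of 163 results tested, 5.52% stood out, about as many as chance gives (1 in 20), and 6 of the 9 had the low library apart.

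The histone list median had a gap of 0.822 of its range, with a library at 10.23 against a median of 10.95 on the log2 scale. The same library had the fewest aligned bases and the lowest ribosome biogenesis mean. Single histone genes with such a low library were HIST1H1B (0.807), HIST1H3H (0.633) and HIST1H4D (0.760). As values of the same libraries, they are not independent of each other or of the list. The stem and progenitor median had a gap of 0.670, with a low value of −2.92 against −2.58. The lymphoid median (gap 1) and the macrophage gene MARCO (gap 1) were at the floor in 5 libraries and above it in 1. The late erythroid minus neutrophil difference had a gap of 0.703, with 1 library at 6.61 against a median of 4.43. The ratio of the long to the short MCL1 transcript (gap 0.894) was low in 1 library, at 2.77, because the minor transcript was listed at 0 in the other 5.

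The first pattern weighed is that short RNAs listed at 0 led the spread between donors. Among genes of 200 nt or less with a mean of at least 5 FPKM, 39.3% (46 of 117) were listed at 0 in at least 1 library, against 0.318% (18 of 5663) of longer genes, which restates the pattern. A separate test, added after that share was known, took the 71 short genes never listed at 0, whose median SD on the log2 scale was 0.56, at percentile 100 of lists of longer genes matched on mean level, with a median of 0.25. Among coding genes listed at 0 in some library, 93.3% (14 of 15) overlapped a transcript of another symbol, HSPE1 among them, against 22.6% of the other coding genes (1254 of 5546; Fisher's exact test, p = 1.15e-08). Genes are not replicates, so the p describes the genes and not donors. These values are consistent with unstable estimates for short RNAs and with reads given to an overlapping transcript, but the wider spread of short RNAs could also be a difference between donors. No biological explanation was tested.

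The second pattern is the spread of ribosome biogenesis genes between donors. A difference in scaling as its sole cause is argued against, since the list stayed at percentile 99.95 of matched lists after median-ratio rescaling. Its median SD was 0.60 against 0.28 for matched lists before rescaling and 0.45 against 0.22 after, so a part played by scaling is not excluded. Depth stays open, since the list mean minus that of matched genes moved with aligned bases over 6 donors (r = 0.794, exact permutation p = 0.0431; rho = 0.657, exact permutation p = 0.175), a relation that rests on the farthest 2 libraries (r = 0.309 without them), while the farthest apart of 4 pairs of like depth differed by 0.57. A candidate explanation is that donors stood at different points of maturation, and r with the late erythroid list was −0.489 (exact permutation p = 0.333) as deposited and −0.897 (exact permutation p = 0.0569) after rescaling, which leaves it open. These p-values weigh r against 0. Random lists matched to the chaperone genes described below had a median r of 0.785 with ribosome biogenesis as deposited and −0.430 after rescaling. Such a background was not computed for lists matched to the late erythroid genes.

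The third pattern is the spread of granulocyte and mast cell genes. Scaling as the sole cause is argued against by its size. The neutrophil list mean ran from −0.07 to 1.59, while the scale factors ran from −0.29 to 0.22 on the log2 scale. Factors of this size could not have removed most of the spread. The SD of the list mean, 0.55 after rescaling against 0.59 before, was therefore largely set in advance. For eosinophil, basophil and mast cell genes only the median SD of members was rescaled, and it was 0.91 against 0.93 before. A varying share of granulocyte precursors in the live gate stays open. In a test set before its value was computed, the 9 neutrophil genes of at least 0.5 FPKM had a mean pairwise r of 0.694 over donors, at percentile 98.8 of matched lists, whose median was 0.253. This rests on the libraries farthest from the median, as r was 0.268 without the farthest 2, against 0.317 for matched lists, and the percentile was 89.1 without the library of lowest neutrophil mean. Without replicate 1 or replicate 2 the genes also lay inside the matched range (percentiles 97.47 and 95.2). Without replicates 3, 5 or 6 they lay above it (99.8, 99.1 and 99.4). LYZ, MPO and ELANE, the most abundant of them, had means of 18.3, 13.8 and 7.29 FPKM, and no other fixed list holds them. A live gate need not remove such cells, and low transcription of these genes in erythroblasts was not tested.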

How the results depend on the processing

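The stricter gene set was added after the data were seen, and all other alternatives were planned. Of the comparisons that answer a question, 111 values were counted as the same, 5 moved and 2 passed a threshold they had missed. For a result with a threshold, the same means the same side of it. A value without a threshold could be counted so although it lay outside its spread, as for the gene counts below. The relation of late erythroid with stem and progenitor genes was reversed, with r 0.788 for list medians. The 7 differences between late erythroid and other lists, the 15 gene pairs and the LMNA and RUNX1 isoform pairs passed under each alternative run for them, with limma run for the gene and isoform pairs only. The count of genes in every library was 4672 with a minimum of 5 FPKM in place of 8455, as fewer genes reach a higher minimum, and 8475 to 8690 with 5 donors. It was 9438 with a minimum of 0.5 FPKM and 9529 with TPM. Both were counted as the same, although the SD of the count per library was 211. The share of the 10 highest genes was 13.6% without globin and noncoding genes, which hold much of the total. Lists above the matched spread numbered 10 in place of 5 after median-ratio scaling, and 3 to 6 when a donor was left out, with 3 without replicate 2. Lists below it numbered 0 to 1, with 1 (histones) without replicate 3. Pearson's r of late erythroid with cell cycle genes was 0.972 after median-ratio scaling and with clearance genes 0.954 for list medians. The cause was not tested. For single lists and gene pairs 483 values were the same, 9 moved, 9 passed a threshold they had missed and 4 no longer passed. Sign-flip tests with 5 donors were not run, since they cannot give p under 0.0625, and relations were not rerun on fewer than 6 donors except as r without the farthest 2. Depth limits all values under about 0.1 FPKM, where a library holds few fragments.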

Other observations

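The 5 gene lists described here were assembled after the data were seen, and so were their tests. Among genes for transporters and adhesion proteins of the red cell membrane, 13 of 14 transport genes and 8 of 11 adhesion and blood group genes had a mean of at least 10 FPKM. These counts were not set against those of all genes or of random lists. BSG, which encodes basigin, stood at 418 ± 59.5 FPKM (SD, n = 6), the scavenger receptor gene CD36 at 256 ± 64.7 FPKM, the nucleoside transporter gene SLC29A1 at 127 ± 17.1 FPKM and the adhesion gene ICAM4 at 73.0 ± 8.65 FPKM. The water channel genes AQP1 and AQP3 stood at 23.1 ± 9.73 and 11.99 ± 5.96 FPKM, and the mechanosensitive channel gene PIEZO1 at 29.1 ± 9.28 FPKM.

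Of the 4 kinases that phosphorylate the translation factor eIF2 alpha, the haem-regulated EIF2AK1 stood at 60.4 ± 9.36 FPKM. EIF2AK2, EIF2AK3 and EIF2AK4 stood at 3.76 ± 0.35, 2.29 ± 0.26 and 7.17 ± 1.90 FPKM. EIF2AK1 exceeded the highest of the others 8.50-fold (log2 difference 3.09 ± 0.58, higher in 6 of 6 donors, exact sign-flip p = 0.03125). Among downstream genes of this pathway ATF4 had 210 ± 19.2 FPKM, PPP1R15A 158 ± 20.5 FPKM, DDIT4 88.0 ± 36.9 FPKM and ASNS 58.9 ± 12.3 FPKM. DDIT3 was listed at 0 in all 6 libraries, which does not show absence. Such a value can be an estimate that gave the reads to an overlapping transcript, and this was not tested for DDIT3.

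A first hypothesis was that integrated stress genes vary more between donors than matched genes. The test was first run on the 12 members with a mean of at least 5 FPKM and gave percentile 99.17, but 3 of its genes, ATF5, TRIB3 and CHAC1, had been chosen because they had been seen to vary. Without these the 9 remaining genes stood at percentile 95.6 of matched lists, inside the range, so the hypothesis stays undecided. After median-ratio scaling they stood at 99.96.

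A second hypothesis was that chaperone genes move with ribosome biogenesis genes between donors. The test took the 12 chaperone genes that had not been seen to lead the first principal component, among them HSPA8 (441 ± 116 FPKM) and HSP90AB1 (144 ± 45.4 FPKM). Their list mean had a Pearson r of 0.985 to the ribosome biogenesis list mean (exact permutation p = 0.00139, the smallest 6 donors allow) and a Spearman rho of 1 (exact permutation p = 0.00278). Pearson's r was 0.966 without the farthest 2 donors and 0.976 after median-ratio scaling. Random lists matched on mean expression had a median r of 0.785 as deposited and −0.430 after scaling, and the chaperone genes stood at percentile 99.6 and 99.7 of them. These lists were not matched on spread. The 12 chaperone genes had a median SD of 0.47 against 0.28 for matched lists as deposited (percentile 99.95). After scaling it was 0.31 against 0.22 (percentile 95.7). Their larger spread can therefore contribute to the percentile of r. With the 4 members seen before, r was 0.986. The list itself was assembled because some of its members led the first principal component. The chaperone mean also moved with aligned bases (r = 0.935, exact permutation p = 0.00833; rho = 0.829, exact permutation p = 0.0583; r = 0.714 without the farthest 2), so a difference between libraries in depth or quality stays open beside a difference between donors or cultures.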
